A study of Mus musculus with 18 samples.

How the data were processed

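DNA from the tails of 9 mice of 1 family and of 1 reference male was measured on 18 two-colour arrays, 2 per mouse with the dyes exchanged. Per the file headers, the scanner output was made with Agilent Feature Extraction 12.1.0.3, on a custom design with positions in build mm9. Per the file headers, the intensity columns hold processed red and green signals that the software had background-subtracted, spatially detrended and dye-normalised with a linear method, beside median spot and background intensities. Per the file headers, the deposited log10 ratio is red over green, and it was used only to check the processed signals. The deposited value table holds log2 ratios that, set against the scanner files, ran as reference over mouse in both dye orientations, with a slope between 0.925 and 1.00 in size and |r| between 0.962 and 1.00. What further correction the authors made to that table is not given in the sources used here. The medians of its columns, with the mouse in Cy3 and then in Cy5, were 0.0021 and 0.0085 for the male parent, 0.0014 and -7.6e-05 for the female parent, 0.0087 and 0.0091 for progeny 1, 0.011 and 0.0088 for progeny 2, -0.00019 and 0.0079 for progeny 3, 0.0016 and 0.0091 for progeny 4, 0.012 and 0.0090 for progeny 5, 0.00015 and -0.00094 for progeny 6, and 0.0022 and -0.00051 for progeny 7. The design text describes an earlier screen on a larger array and a later check by TaqMan copy number assays, neither of which was analysed here.

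Each array had 151683 spots, of which 6563 control spots were left out. The remaining 145120 spots belonged to 141072 probes, 1029 of them in several spots. Spots that the scanner software marked as non-uniform or as population outliers were left out, between 0.0627% and 0.12% per array, and 180 probes without a value on every array were dropped. The log2 ratio of the processed red over green signals was centred on the array median, turned to mouse over reference from the dyes in the labels, averaged over the spots of a probe and centred on the median again. No loess or quantile step was applied. The 2 arrays of a mouse were averaged and counted as 1 replicate. The median spot signal lay between 296 and 814 in green and between 397 and 1274 in red, and the number of arrays limits the precision. The arrays of the parents were the dimmest, between 296 and 399.5 in green and between 397 and 498 in red. Those of the progeny lay between 472.5 and 814 in green and between 730.5 and 1274 in red. With the mouse in Cy5 and in Cy3, the X ratio of the female parent was 0.89 and 1.01, which checked the direction.

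Each track was segmented by penalised least squares (PELT), with a penalty of 4 ln(n) times the noise variance and at least 5 probes per segment. A call needed a mean of at least 0.3 in size and at least 0.2 with the same sign in each orientation. Overlapping calls of 1 direction were merged, and a mouse carried a merged region when its mean passed the same limits. A region was parental when a parent carried it, and of progeny alone when both parents were under 0.15 in size. Of the 91 merged regions, 2 were in all 9 mice, 32 parental, 30 of progeny alone and 27 in none of these classes. Transmission was tested with an exact two-sided binomial test with Benjamini-Hochberg adjustment, and calls per mouse with an exact two-sided permutation test. Probes were tested with limma 3.58.1 in R 4.3.3, in 1 fit with 3 groups, at an adjusted p under 0.05 and a difference of at least 0.3. Other steps used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and numba 0.67.0.

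The caller was tested on simulated data with independent noise at the level of each mouse over 140892 probes. It found 100% of 198 segments at each of 3 lengths (5, 10 and 30 probes) and 3 levels, with 0 false calls in 9 mice. That simulation left out dye bias and effects shared by neighbouring probes. The dye track, the mean of the 2 arrays of a mouse before turning, covers these in part. The simulated noise was normal, so it also left out single probes far from their neighbours. In the data some calls of 5 probes varied widely, such as chromosome 2 from 81249688 in the female parent, with an SE over probes of 0.48. The 0 false calls therefore say little about calls of 5 probes. A second simulation, of limma, gave every mouse the same spread at a probe, although the parents were noisier than the progeny. Its false calls therefore say little about the parental counts. For the male parent against progeny, limma recovered 84% of 100 simulated changes of 0.5 and 98% of 100 changes of 1 over 140892 probes, with 3 false calls.

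The tests, the alternatives and the rule for named regions were fixed before the data were examined. The rule took, in each of 3 kinds (all 9 mice, parental, progeny alone), the 8 regions with the largest mean in a carrier, and up to 15 regions carried by exactly 1 progeny mouse, which gave 26. Named regions were not recomputed under the limits of the caller or without single mice, since their means do not depend on these. The alternatives were normexp with an offset of 50, the deposited value table, marked spots kept, dim probes left out, centring on the mean of the middle 50% of probes, either dye orientation alone, penalties of 2 and 8, limits of 0.25 and 0.5, minima of 3 and 10 probes, slide as a random block in limma, no minimum difference, and leaving out each progeny mouse. The normexp alternative used median spot signals in place of mean signals. An autosomal run, a run without calls whose neighbouring probes lie over 20 kb apart, and the transmission tests without regions called in all 9 mice or turned in sign by normexp, and without those under 0.15 in size with normexp too, were added after seeing the data. The correction for GC content and the count of gene classes were not run, since no probe sequences were used and the gene table given belongs to another build. For the same reason no gene was named for any region.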

Results

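Copy number was measured by array comparative genomic hybridisation, in which DNA of a mouse and DNA of a reference animal carry different dyes and compete for the same probes. The mice were 1 C57BL/6JNrs family: the male parent, the female parent and 7 progeny, with DNA prepared from the tail. Each mouse was hybridised against the same reference male on 2 arrays with the dyes exchanged, which gave 18 arrays that count as 9 replicates. The title of the series concerns males exposed to gamma rays at 0.05 mGy per day for 400 days, whereas its design text calls the male of this family non-irradiated, so no statement about exposure was made here. After spots marked as outliers by the scanner software were left out, 140892 probes remained, of which 48 lay on X and 3 on Y. The probes were dense at places picked in an earlier screen of the study, so the counts of regions were not rates per genome. Between 99.6% and 99.9% of spots on each array were well above background in either channel. All ratios are log2 of mouse over reference male, 0 is an equal copy number, and positions are in build mm9.

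The clearest inherited change was a loss on chromosome 10 from 8066869 to 8070061, covered by 32 probes over 3.19 kb. The male parent carried it at -0.90 ± 0.03 (SE over probes), with -0.85 in Cy5 and -0.94 in Cy3. Progeny 1 was at -0.86 ± 0.02, progeny 3 at -0.89 ± 0.02 and progeny 6 at -0.87 ± 0.03 over the same probes. The female parent was at 0.00 ± 0.01, and progeny 2, 4, 5 and 7 were at 0.01, 0.01, -0.01 and -0.01. Probes ending at 8066547 and starting at 8071159 bounded it on either side. Thus 3 of 7 progeny carried the paternal loss, with an exact two-sided binomial p of 1 against equal chances (adjusted p = 1 over 23 tests).

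The question of the series was whether progeny hold changes that their parents lack. The change of this kind with the most probes was a loss on chromosome 14 from 87133149 to 87139762, covered by 68 probes over 6.61 kb, in progeny 1. Progeny 1 was at -0.47 ± 0.01 (SE over probes), with -0.49 in Cy5 and -0.46 in Cy3. The male parent was at 0.02 ± 0.01 and the female parent at 0.00 ± 0.01, and the other 6 progeny lay between -0.01 and 0.02. The nearest probe to the left ended at 87132244, and the next to the right started at 87232067, so the right end of the loss was not bounded closely. In the same mouse the paternal chromosome 10 loss was deeper, at -0.86.

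**Figure D1:**
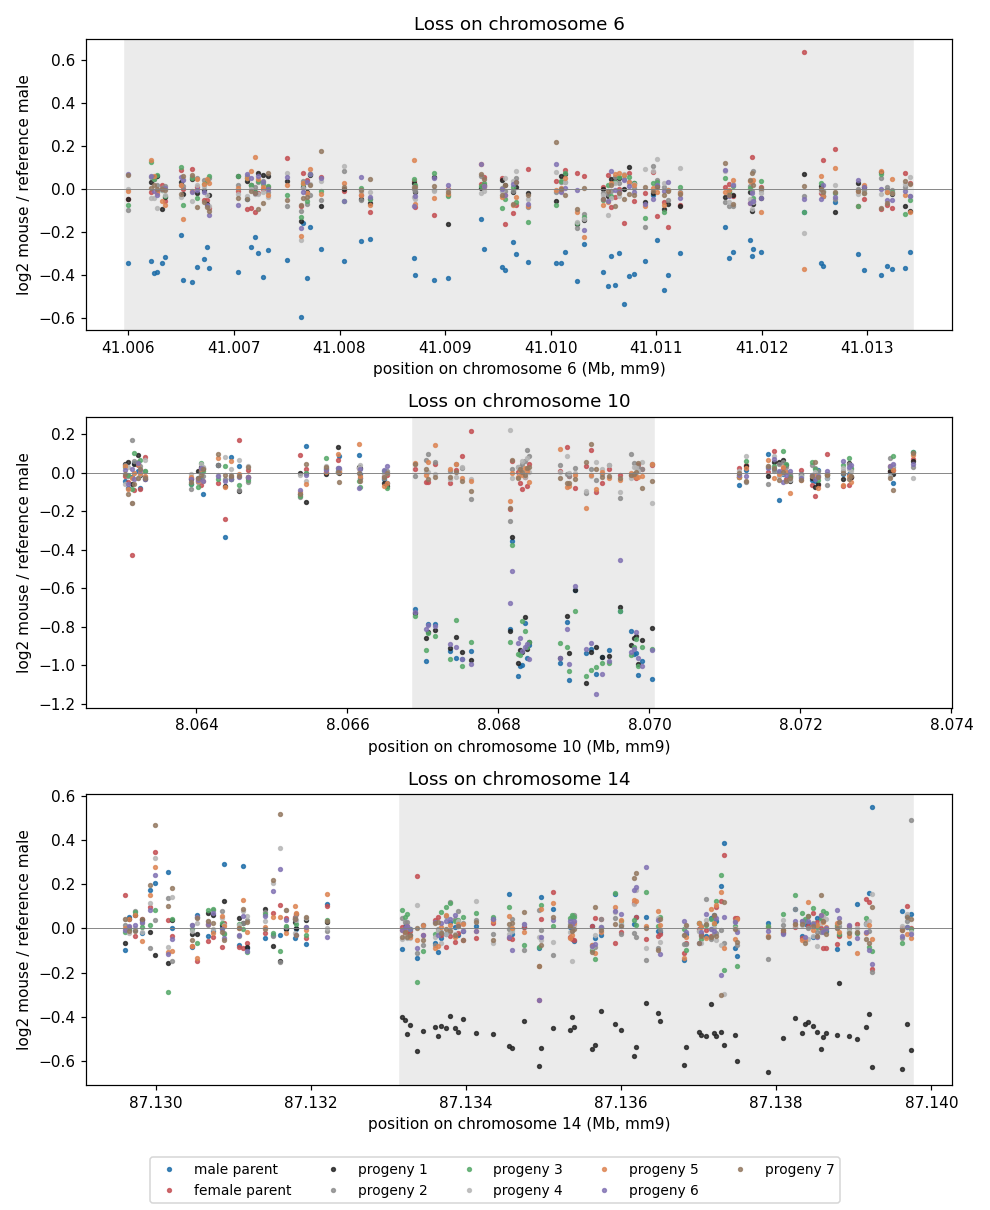
Log2 ratio of mouse over reference male (y axis) at single probes along chromosomes 6, 10 and 14 (x axis, Mb, mm9), each point the mean of the 2 arrays of 1 mouse, with the called region shaded. The chromosome 10 loss is seen in the male parent and progeny 1, 3 and 6, the chromosome 14 loss in progeny 1, and the chromosome 6 loss in the male parent.

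In all, 30 merged regions were carried by progeny with both parents under 0.15 in size, 28 gains and 2 losses. The other loss was on chromosome 12 from 51375903 to 51376456, where 5 probes gave -0.35 ± 0.25 (SE over probes) in progeny 3. Progeny 7 carried 23 of the 30 regions, all gains, and without this mouse the count was 8. The female parent lay between 0.07 and 0.15 over these 23, so their place in this class rests on the limit of 0.15, and at 21 other gains of progeny 7, between 0.16 and 0.32 in the female parent, the class was left open. Most gains of progeny 7 were short, such as chromosome 7 from 78386104 to 78386611 at 0.43 ± 0.09, chromosome 5 from 37142318 to 37142784 at 0.37 ± 0.07 and chromosome 12 from 82960663 to 82962474 at 0.37 ± 0.21. Further gains of progeny 7 over 5 probes, with SEs over probes between 0.14 and 0.20, lay on chromosome 1 from 116902876 (0.36), chromosome 3 from 78963806 (0.33), chromosome 5 from 39639884 (0.34) and from 89627026 (0.35), and chromosome 18 from 42379452 (0.34). The 5 probes of a gain on chromosome 2 from 22980499 to 25111830 (0.35 ± 0.22) were spread over 2131 kb, with up to 826093 bp between neighbours, and with normexp it was at 0.17. At chromosome 18 from 53499641, both progeny 4 (0.31) and progeny 7 (0.39) carried a gain. At the chromosome 7 site from 78386104, progeny 4 was at 0.27 and progeny 6 at 0.22, below the limit for a carrier, and progeny 1 was at -0.17. On chromosome 5 from 37142318 these mice were at 0.21, 0.24 and -0.08. On chromosome 1 from 116902876 they were at 0.25, 0.19 and -0.14. That progeny 7 alone counted as a carrier there thus rests on the limit of 0.3. Progeny 4 carried gains on chromosome 2 from 100379943 (0.36 ± 0.10, 6 probes) and chromosome 11 from 76357379 (0.36 ± 0.10). Progeny 3 carried one on chromosome 4 from 30873696 (0.40 ± 0.19, 9 probes) and progeny 6 one on chromosome 7 from 47257271 (0.74 ± 0.39). With normexp background correction these last gains were at -0.06 and -0.02, and those on chromosomes 2 and 11 in progeny 4 were at 0.01 and 0.02. The region on chromosome 4 from 30873696 also merged gain calls of progeny 7 (0.41) and of the male parent (0.31). The latter adjoined it, from 30874449 to 30875618. It counted as of progeny alone because the male parent was at 0.04 over the 9 probes of progeny 3, so absence from the parents is not established there. The chromosome 12 loss of progeny 3 was at -0.09 with normexp, and without dim probes the chromosome 11 gain of progeny 4 was at 0.15. Only 2 of the 30 regions held at least 10 probes, the chromosome 14 loss and a gain on chromosome 4 from 30867559 in progeny 3 (0.31 ± 0.08), the latter chosen for naming after its values were seen. These regions were described without a test.

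Parents carried 32 regions that were not in all 9 mice, 21 gains, with X among them, and 11 losses. The male parent was the only parental carrier of 10 of them, the female parent of 13, and both parents carried 9. A loss on chromosome 6 from 41005970 to 41013431, with 77 probes that span 7.46 kb, was in the male parent at -0.32 ± 0.01 (SE over probes), with -0.35 in Cy5 and -0.29 in Cy3. The nearest probes outside ended at 40612734 and started at 41634774, so neither end was bounded closely. The other 8 mice lay between -0.01 and 0.00 there; this region was chosen for naming after its values were seen. On chromosome 3 from 25421508 to 25443259, 10 probes were at -1.27 ± 0.34 in the female parent, and at -1.49, -1.48, -1.43 and -1.53 in progeny 4, 5, 6 and 7. The male parent was at 0.03 and progeny 1, 2 and 3 were at 0.01, -0.04 and 0.00. The carriers of this loss were those of the X gain, so it is not read as an inherited change. A loss on chromosome 2 from 81249688 was in the female parent (-0.59 ± 0.48) and a loss on chromosome 11 from 76358669 in the male parent (-0.50 ± 0.23). Over the latter the female parent, on the same slide, was at -0.26, under the limit for a carrier. Progeny 6 was at -0.06 there and the other progeny lay between 0.08 and 0.18. Gains in a parent included chromosome 11 from 29140726, at 0.50 ± 0.12 in the female parent and 0.38 in progeny 1, where the male parent (0.49) and progeny 5 (0.43) missed the limit in Cy5. Another was chromosome 15 from 92612514, at 0.48 ± 0.03 in progeny 5, 0.42 in progeny 1, 0.33 in progeny 3, 0.40 in the male parent and 0.42 in the female parent. On chromosome 12 from 80313562 the gain was 0.62 ± 0.16 in progeny 7, 0.39 in progeny 4, 0.35 in progeny 6 and 0.30 in the female parent. With normexp the chromosome 11 loss from 76358669 was at 0.01, the chromosome 2 loss at -0.21, the chromosome 11 gain from 29140726 at 0.18, and the count of parental regions was 13. Of the 23 regions with 1 parental carrier, 8 had no carrier among the 7 progeny, each with an exact two-sided binomial p of 0.0156 (adjusted p = 0.0449), the smallest the test can give. The test takes each region for a one-copy change in that parent, which these values do not establish, so it is not read as a lack of transmission. Of the 8, 5 rested on 5 probes with an SE over probes between 0.22 and 0.48, the chromosome 6 loss was shallower than the chromosome 10 loss of the same mouse, and the region on chromosome 14 from 54151351 had loss calls in every mouse. With normexp all 8 were under the limit of 0.3 in that parent, and 5 were under 0.15, among them the loss on chromosome 2 from 100379270 with 7 probes (-0.41, and -0.01 with normexp). Normexp also shrank well-covered changes, the chromosome 10 loss in the male parent from -0.90 to -0.79 and X in the female parent from 0.95 to 0.82. The chromosome 6 loss went from -0.32 to -0.29, so a value under 0.3 with normexp does not by itself mark a false call. Without the chromosome 14 region and the chromosome 11 loss that turned with normexp, the smallest adjusted binomial p was 0.0547. Without all regions under 0.15 with normexp as well it was 0.125. Both sets were left out after seeing the data. Regions without a progeny carrier share the smallest possible p, so leaving such regions out raises the smallest adjusted p by itself.

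Both regions carried by all 9 mice were losses on chromosome 14. From 53708609 to 53764803, 45 probes lay between -0.78 (progeny 5) and -0.83 (progeny 4), with the parents at -0.80 and -0.80. From 53981522 to 53989116, 18 probes were at -0.65 ± 0.05 in the male parent, -0.47 ± 0.03 in the female parent and between -0.48 and -0.56 in the progeny; with normexp the male parent was at -0.36. Further along, from 54151351 to 54705309, the male parent had 1 loss call over 97 probes, at -0.38 ± 0.02. The other 8 mice had several shorter loss calls within or across this span, such as 11, 7 and 5 probes in the female parent. Their means over the 97 probes were between -0.25 and -0.29, under the limit for a carrier, so this region counted as parental although the progeny had losses there. Since all ratios share the reference male, a shift in every mouse can stem from that animal. Gene classes were not counted, so whether these losses or the chromosome 6 loss of the male parent hold antigen receptor genes, which lymphocytes rearrange, was not analysed here. With calls that span gaps over 20 kb left out, an alternative added after seeing the data, the count of regions in all 9 mice was 7.

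The X chromosome was at 0.95 in the female parent, and at 0.95, 0.95, 0.95 and 0.96 in progeny 4, 5, 6 and 7. Progeny 1, 2 and 3 were at -0.0012, 0.0016 and -0.0047. The male parent was at 0.26 ± 0.07 (SD over 48 probes), with 0.20 in Cy5 and 0.32 in Cy3. The labels used here did not give the sex of the progeny. The first Y probe was at 0.03 in the male parent, -4.95 in the female parent, -0.07, -0.05 and 0.01 in progeny 1, 2 and 3, and -5.71, -5.73, -5.46 and -5.83 in progeny 4, 5, 6 and 7. Progeny 4 to 7 thus shared the X and Y levels of the female parent, and progeny 1 to 3 lay near the reference male on both. The X region, counted above as a parental gain, is therefore not read as an inherited copy-number change. Of the 11 parental losses, 4, on chromosomes 3, 5, 6 and 11, had exactly the 5 carriers of the X gain. These were the mice low at the first Y probe, so the transmission tests of these losses followed the X and Y levels. The 4 losses are therefore not read as inherited copy-number changes either. A loss on chromosome 9 from 35856771 leaned the same way, at -0.34 in the female parent and -0.29, -0.27, -0.33 and -0.26 in progeny 4 to 7. The male parent and progeny 1 to 3 lay between -0.03 and 0.01 there. By the limit of 0.3 only the female parent and progeny 6 counted as its carriers.

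**Figure D2:**
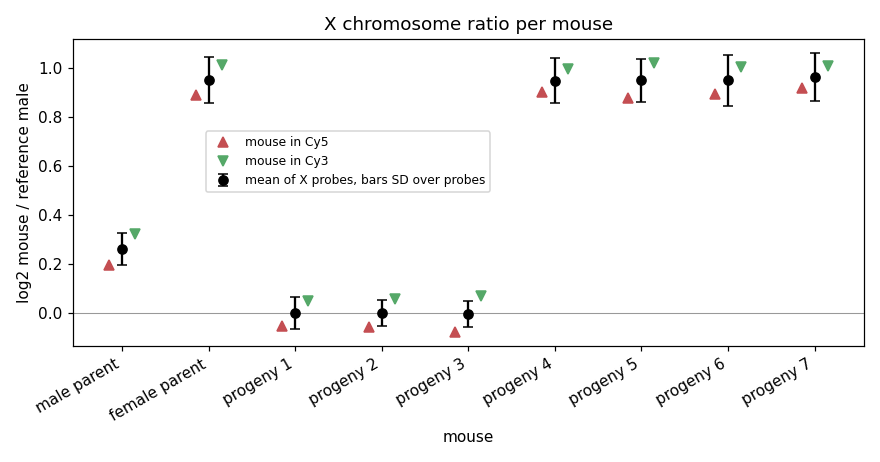
Mean log2 ratio of mouse over reference male (y axis) of the 48 X probes in each of the 9 mice (x axis), with bars for the SD over probes and triangles for the array with the mouse in Cy5 and in Cy3. The male parent sits at 0.26, between progeny 1 to 3 near 0 and the female parent and progeny 4 to 7 near 0.95.

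Calls per mouse numbered 24 in the male parent, 29 in the female parent and 24, 9, 15, 29, 31, 23 and 67 in progeny 1 to 7. The mean was 28.3 ± 18.7 (SD, n = 7) in progeny and 26.5 in the 2 parents, a difference of 1.79 with an exact two-sided permutation p of 0.889 over 36 splits. Without progeny 7 the difference was -4.67 (exact permutation p = 0.679). The mean of the 2 arrays of a mouse before they were turned, called the dye track here, in which copy number cancels, gave between 2 and 6 calls per mouse, 34 in total against 251. This total moved with the setting, to 129 with a penalty of 2, 5 with a penalty of 8, 9 with normexp and 2 without dim probes. A response that belongs to a DNA sample cancels in the dye track as copy number does. The penalty also followed the noise of each track. The dye track therefore does not bound the false calls among the 251. Of the 251 calls, 58 held at least 10 probes. Calls are segments, so 1 change could give several. The loss on chromosome 14 from 53708609 was a single call of 45 probes in both parents. In progeny 4 it was split into calls of 8, 14, 5 and 18 probes. X and the losses with the same carriers added calls only in the 5 mice with X near 0.95. The calls thus do not count separate changes, and their difference depends in part on splitting and on X and Y levels. Both parents lay on 1 slide of their own, so slide and generation cannot be told apart. The arrays of that slide were also the dimmest in both channels.

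**Figure D3:**
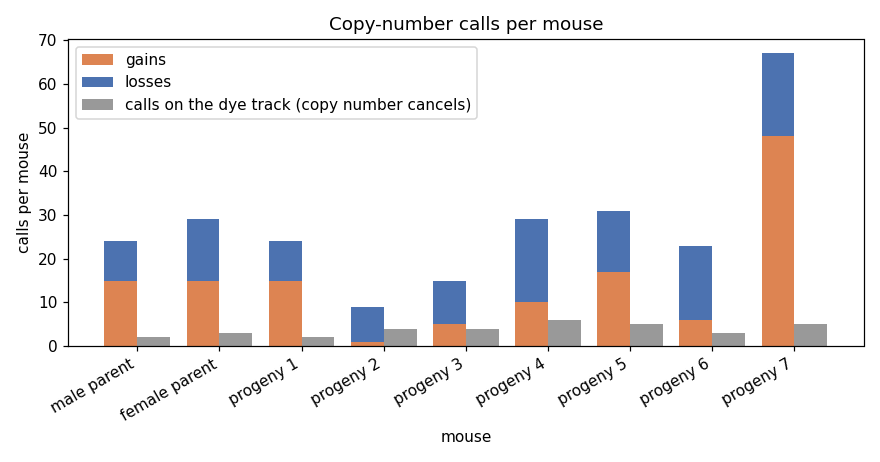
Number of calls (y axis) in each of the 9 mice (x axis), stacked as gains and losses, beside the calls that the same procedure made on the dye track, the mean of the 2 arrays before they were turned. Progeny 7 has 67 calls, 48 of them gains, and the dye track gives at most 6 calls in any mouse. The dye track does not bound the false calls.

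Single probes were compared with limma. Against the progeny, 320 probes differed in the male parent, 224 higher and 96 lower. Of these, 38 lay in the chromosome 6 loss from 41005970 and 18 in the chromosome 14 region from 54151351, while 258 lay outside all merged regions. In the female parent 93 probes differed, 83 higher and 10 lower, of which 90 lay outside the merged regions. Without progeny 1, 2, 3 or 4 the female count was 55, 58, 48 and 55. With normexp the male count was 12, with 3 higher and 9 lower, and the female count 1, a lower probe. Progeny differed from the reference male at 125 probes, 2 higher and 123 lower. Of these, 44 lay in the chromosome 14 region from 53708609, 44 in that from 54151351 and 16 in that from 53981522. Single arrays gave other counts: with the mouse in Cy5 alone, the male, female and progeny counts were 496, 1773 and 2719, and in Cy3 alone 1070, 23 and 2286. With 1 mouse as a parent group, its spread was taken to be that of the progeny, but the noise SD was 0.0698 in the male and 0.0669 in the female parent and between 0.0445 and 0.0583 in the progeny. The parents were thus noisier than the fit assumed, and their counts are not firm. Their arrays were also dimmer in both channels than those of the progeny. Whether this bears on the fall of their counts with normexp was not tested.

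After both arrays of a mouse were turned to mouse over reference, Pearson's r across all probes lay between -0.56 in progeny 2 and -0.25 in progeny 7. Turning reverses the sign of a dye effect in 1 of the 2 arrays, so dye effects pull r below 0. How much of the negative r they account for was not tested. The r of progeny 7 was the highest, not the lowest, of all mice. Over the 836 probes in merged regions, r lay between 0.49 and 0.81, but calls needed the same sign in both orientations, so the choice of these probes favours a positive r. These correlations are across probes of 1 mouse, and probes are not independent replicates.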

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

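Among the 7 progeny, 35 sets of values were searched for a mouse far from the others. Of 9 sets that did not depend on a chosen region, 3 held such a mouse, where chance gives about 1 in 20, but gains are part of calls, and r passed the critical value of 0.568 only within its rounding. The other 26 sets were named regions, picked for the size of the change in a mouse, so that no chance rate applies to the 5 found there. The tests of explanations were chosen after the result was seen, except that on components of uncalled probes and that on the spread between probes in the chromosome 14 loss.

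Progeny 7 stood apart with 67 calls, with 48 gains, and with r = -0.25 between its 2 arrays. Of 69 autosomal gains under 10 probes at scattered sites, 48 had 1 carrier, which was progeny 7 at 40. At others, such as chromosome 16 from 21547959, the parents and progeny 1 and 5 were the carriers. A single carrier depends on the limit of 0.3 and does not mark a gain as private to progeny 7. For example, progeny 4 and 6 were at 0.21 and 0.24 on chromosome 5 from 37142318, with progeny 1 at -0.08. One extra copy in every cell of the carriers was argued against for the regions as a set, since the highest mouse had a median of 0.35 with an SD of 0.078 over regions, below the 0.56 that an extra copy would give if these probes respond as those on X, but 3 of the 69 reached that level and are not excluded, although the highest, 0.74 ± 0.39 (SE over probes) on chromosome 7 from 47257271 in progeny 6, was at -0.02 with normexp. A probe response that differs between DNA samples across the genome stays possible, but the test run cannot decide it. The 2 leading components of 26447 uncalled bins held a median of 0.89 of the variance of these regions between mice. In the uncalled bins themselves the median was 0.49. The regions were picked for large values and the bins were not, which can raise this share whatever the cause. Component 1 also weighed progeny 7 most (0.50), the only carrier at 40 of the regions. Slide cannot be told apart from progeny 7, the lone mouse on its slide: differences within a slide were 0.86 of those between slides, but none of the 4 pairs within a slide held progeny 7; no other biological explanation was tested.

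Progeny 1 was at -0.47 over the chromosome 14 loss from 87133149, far from the other 6 progeny. Noise or dye bias was argued against, since the largest segment of at least 20 probes in the dye tracks of the 9 mice, in which copy number cancels, reached 0.25 in size. A mixture of lost and retained probes was argued against too, as the SD over probes was 0.90 of the median SD of the other 8 mice. The level lay 0.38 ± 0.03 (SE) above that of the paternal chromosome 10 loss in the same mouse, which argues against a one-copy loss in every cell if both sets of probes respond alike. A one-copy loss in part of the cells, 63.6% on that scale, stays open as a hypothesis, as does a weaker response of these probes, and neither was tested.

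Progeny 4 was at 0.36 over chromosome 2 from 100379943 and 0.36 over chromosome 11 from 76357379, apart from the other progeny by gaps of 0.572 and 0.573 of the range, just past 0.568, and with normexp it was at 0.01 and 0.02. Progeny 6 was at -0.064 over chromosome 11 from 76358669, below the other 6 progeny. Progeny 3 was at -0.35 over chromosome 12 from 51375903, and at -0.09 with normexp.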

How the results depend on the processing

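The autosomal run, the run without wide gaps and the transmission tests on fewer regions were chosen after seeing the data. The last moved the smallest adjusted binomial p from 0.0449 in 23 tests to 0.0547 in 21 and 0.125 in 16. That rise followed from the choice, since the 2 regions first left out had no progeny carrier. Nor did 5 of the 6 regions under 0.15 with normexp. Of 172 values under alternatives, 130 kept their result, which for a count means within 1.5 times, for the correlation of the orientations within 1 SD over mice, and for the difference in calls only its sign and its side of the threshold. For the rest the cause was not tested. Normexp also shrank clear changes, such as X in the female parent from 0.95 to 0.82, while the limits stayed fixed. With normexp there were 13 parental regions and 4 regions in all 9 mice, and limma called 12 probes in the male and 1 in the female parent. Cy5 alone gave 16.0 calls per mouse, 6 regions of progeny alone, 1 region in all 9 mice, and 496, 1773 and 2719 probes for the male parent, female parent and progeny. Cy3 alone gave 14.2 calls per mouse, 7, 1, and 1070, 23 and 2286. A limit of 0.25 gave 70 regions of progeny alone, while 0.5 gave 8.11 calls per mouse, 1 region of progeny alone and 11 parental regions. A minimum of 3 probes gave 72.7 calls per mouse, 86 regions of progeny alone, 59 parental regions and 4 in all 9 mice; 10 probes gave 10, 4 and 9 for the first 3 of these. A penalty of 2 gave 4 regions in all 9 mice, leaving out wide gaps gave 7, and no minimum difference gave 565 probes in progeny.

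The difference in calls between progeny and parents, 1.79, turned to -1.07 with the value table, -0.36 with Cy3 alone, -0.57 with a penalty of 2 and -1.29 with 10 probes. With its sign kept it was 37.5 with 3 probes, 14.6 with a limit of 0.25, 13.6 with normexp, 9.21 with a penalty of 8 and 4.57 without dim probes, so its size is not fixed by these data. Leaving out 1 progeny mouse gave between -4.67 (without progeny 7) and 5, and over all 22 alternatives the exact permutation p lay between 0.444 and 1. Leaving out 1 progeny mouse gave 8 (without progeny 7) to 30 regions of progeny alone and 48 (without progeny 3) to 74 probes in the female parent, with 55, 58 and 55 without progeny 1, 2 and 4. Of 26 named regions, 23 kept their sign in all settings run. With normexp, chromosome 4 from 30873696 was at -0.064, chromosome 7 from 47257271 at -0.015 and chromosome 11 from 76358669 at 0.0051. A carrier had to hold the sign in both orientations, so the settings with either orientation alone could not turn it. Kept signs also include values near 0, such as 0.014 on chromosome 2 from 100379943 and 0.017 on chromosome 11 from 76357379. The 23 is therefore weak evidence that these regions are stable. Not run were the GC correction and the gene classes. No paired analysis was possible because each parent group holds 1 mouse. Calls on the dye track, 34 in total, were 129 and 5 with penalties of 2 and 8, 9 with normexp and 2 without dim probes. At least 99.6% of spots per array were well above background, yet leaving out the dim probes (140287 stayed) gave 24 parental regions against 32 and 257 limma probes in the male parent against 320.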

Other observations

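The tests below were chosen after the result was seen.

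Several short autosomal losses were found in the same mice as the chromosome 3 loss from 25421508. These are the 5 mice with X near 0.95 and the first Y probe at -4.95 or lower. The losses thus followed the X and Y levels in all 9 mice and are not read as inherited copy-number changes. On chromosome 5 from 123597144, the female parent was at -0.42 and progeny 4, 5, 6 and 7 were at -0.36, -0.38, -0.36 and -0.39. On chromosome 6 from 104241140 these mice were at -0.34, -0.37, -0.33, -0.36 and -0.34, and on chromosome 11 from 112960611 at -0.46, -0.32, -0.41, -0.39 and -0.41. The male parent was at -0.06, 0.05 and -0.02 over these 3 regions. Each rests on 5 probes that differed widely, with an SE over probes of 0.34 in the female parent on chromosome 5, 0.35 in progeny 4 on chromosome 6 and 0.39 in the female parent on chromosome 11. These regions were chosen after their values were seen.

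The X ratio of the male parent, 0.26, lay between the levels of progeny 1 to 3 and of the female parent. Admixture of DNA with 2 X chromosomes and no Y was argued against, since 2 of the 3 Y probes, those lowest in the female parent, had a mean of 0.037 where a share of 20.8% would give -0.32. The third Y probe, at -0.47 in the female parent, responded little; with it the mean was 0.011. Admixture of DNA without the chromosome 10 loss was argued against as well, with the loss at -0.90 where dilution of the deepest progeny value would give -0.64. Dye bias or noise of 1 array was argued against, since the lower orientation was at 0.20 and all 48 probes were above 0; no biological explanation was tested.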
